A study of Mus musculus with 12 samples.

How the data were processed

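RNA from seminal vesicles of male C57BL/6 mice at week 10 was measured on Affymetrix arrays, 12 in all, 3 in each of 4 groups (WT_vehicle, WT_DES, aERKO_vehicle and aERKO_DES). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and 300 ng were amplified and labelled with biotin. The labels do not say that the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The deposited values are log2 expression per probe set made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA subtracts background, equalizes the distribution of values between arrays and summarizes the probes of a set. Versions, settings and the genome build are not given in the sources used here, so no coordinates are given. Because the arrays had already been normalized to one another, a broad change in total RNA or a large block of rising genes can push unchanged genes slightly the other way.

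The table held 72688 probe sets, of which 186 were array controls. The platform annotation gave exactly 1 gene symbol for 30604 probe sets, several for 2146 and none for 39938. Only those with 1 symbol were named, and 1135 symbols were updated through the mouse gene table of assembly GRCm38.p6. This gave 30063 genes, 429 of them with more than 1 probe set. Such a gene was represented by the probe set with the highest mean over the 12 arrays. Genes were tested where the value exceeded the array's median over all probe sets on at least 3 of the 12 arrays, which kept 20102 and removed 9961.

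Differential expression was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a mean per group, all 12 arrays in 1 fit, two-sided tests and Benjamini-Hochberg adjustment over the genes tested within each comparison. The threshold was an adjusted p of 0.05. The fit had 8 residual and 4.33 prior degrees of freedom. The 5 comparisons were DES against vehicle in WT, the same in aERKO, the difference between these 2 responses, aERKO against WT given vehicle, and aERKO against WT given DES. Standard errors (SE) come from limma and SDs from the arrays of a group. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1 and was not used for single genes.

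Gene lists of tissue functions, cell types and neighbouring tissues were written before the data were examined, as were the groups, the tests and thresholds, the rule for named genes and the alternatives listed first below. The 30 lists held 629 entries, of which 563 were named on the array and 529 tested. The red blood cell list had 2 testable members, fewer than the 3 needed, and its members' median after DES in WT was -0.33. Each of the other 29 lists was tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, and its members were counted over all genes tested and adjusted over the list alone. Camera compares a list with the other genes, whereas fry asks whether its own genes move one way.

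Named genes follow the fixed rule: for each comparison the 12 largest increases and 12 largest decreases among called genes whose 2 groups do not overlap (without that condition for the interaction), leaving out provisional names, small RNAs and immunoglobulin or T cell receptor segments; up to 4 members with the largest called differences in each list; and fixed genes, among them Esr1, Esr2, Pgr, Ltf and Svs4. Not all of these are printed. Mid1, Nt5c2, Spock1, Igkv5-43 and Trbv20 fall outside it and were chosen after their values were seen.

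Alternatives changed 1 choice at a time: no filter or a stricter one, which kept 12519 genes, the mean of all probe sets of a gene, every probe set tested, a trend and robust moderation, only the 2 groups compared, array weights, quantile normalization, shifting arrays to the same median or 75th percentile, the replicate number as a block, a fold of at least 2, and each array left out in turn. After the data were seen, a shift to the 4 hybridization controls, leaving out both DES arrays numbered 3, and a comparison of all 6 aERKO arrays with WT_vehicle were added.

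Of the tests of explanations in the closing section, 3 replaced earlier versions whose outcomes had been seen. For array-wide scaling and the immune genes, the first version counted genes at least 2-fold higher that kept their call after the shift to the hybridization controls. It gave 922 of 922, and it was dropped because that shift raises WT_DES and so could not have ended these calls. The test in its place compares the immune lists with the median of all genes. For array-wide scaling and the small declines, 243 of 4570 calls kept with the hybridization controls had first been read in favour of scaling. A second version added the median scaling, which lowers WT_DES and so could not have ended these calls. The share is now read as deciding nothing, because the shift exceeds the median decline. For uniform dilution the first version compared luminal epithelial with smooth muscle genes, whose difference of 0.372 lay under 3 times its SD and left dilution open. Endothelial genes took the place of luminal genes when the list medians were already known, with the bound kept at 3 times the SD. The other bounds were also set after these values were known.

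The test procedure was tested on simulated data with known changes in each comparison, on the same 20102 genes. Each comparison held 50 changed genes of each size, 0.5, 1, 2 and 3, with independent noise between genes. The larger changes ease the adjusted threshold, so the shares recovered do not carry over to a comparison with few or no changed genes. For DES in WT it recovered 58% of genes with a log2 change of 0.5 and 100% of those with 1, 2 and 3. For DES in aERKO the shares were 66% at 0.5, 96% at 1 and 100% above. For the difference between genotypes they were 30%, 88% and 100%, for genotype given vehicle 76%, 94% and 100%, and for genotype given DES 64%, 96% and 100%. The simulated comparisons gave 11, 6, 8, 13 and 8 false calls. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.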

Results

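Gene expression was measured in the seminal vesicles of male mice at week 10, in a 2 by 2 design of genotype and neonatal treatment. Male pups received diethylstilbestrol (DES), a synthetic estrogen, under the skin at 2 µg per pup per day on days 1 to 5 of life, or corn oil alone (vehicle). The mice were wild type (WT) or lacked estrogen receptor alpha (aERKO), the receptor encoded by Esr1. The 4 groups, WT_vehicle, WT_DES, aERKO_vehicle and aERKO_DES, held 3 arrays each, 12 in all. The design asks which genes of the adult gland differ after DES exposure in the first days of life, and whether that response depends on estrogen receptor alpha. Array medians lay between 5.95 and 6.14 on the log2 scale. Pairs of arrays within a group correlated at 0.982 to 0.996 across genes, and pairs among the 9 arrays outside WT_DES at 0.983 to 0.997. Pairs of a WT_DES array with an array of another group correlated at 0.867 to 0.919. The first principal component held 83.8% of the variance and set the WT_DES arrays apart from the other 9. The number of arrays limits the precision of every value given here.

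Esr1, the targeted gene, was lower in all 6 aERKO arrays than in all 6 WT arrays. Its level was 7.75 ± 0.0795 (SD, n = 3) in WT_vehicle, 7.66 ± 0.0965 in WT_DES, 6.99 ± 0.106 in aERKO_vehicle and 6.90 ± 0.0904 in aERKO_DES. The log2 difference between genotypes was -0.76 ± 0.08 (SE) given vehicle, with an adjusted p of 0.00587. Given DES it was also -0.76, with an adjusted p of 1.06e-05. The array reports 1 summary of the whole Esr1 transcript, which can include parts that a targeted allele leaves in place, so the remaining signal is no measure of intact receptor mRNA. DES left Esr1 without a detected difference in WT (log2 -0.09, adjusted p = 0.351).

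**Figure D1:**
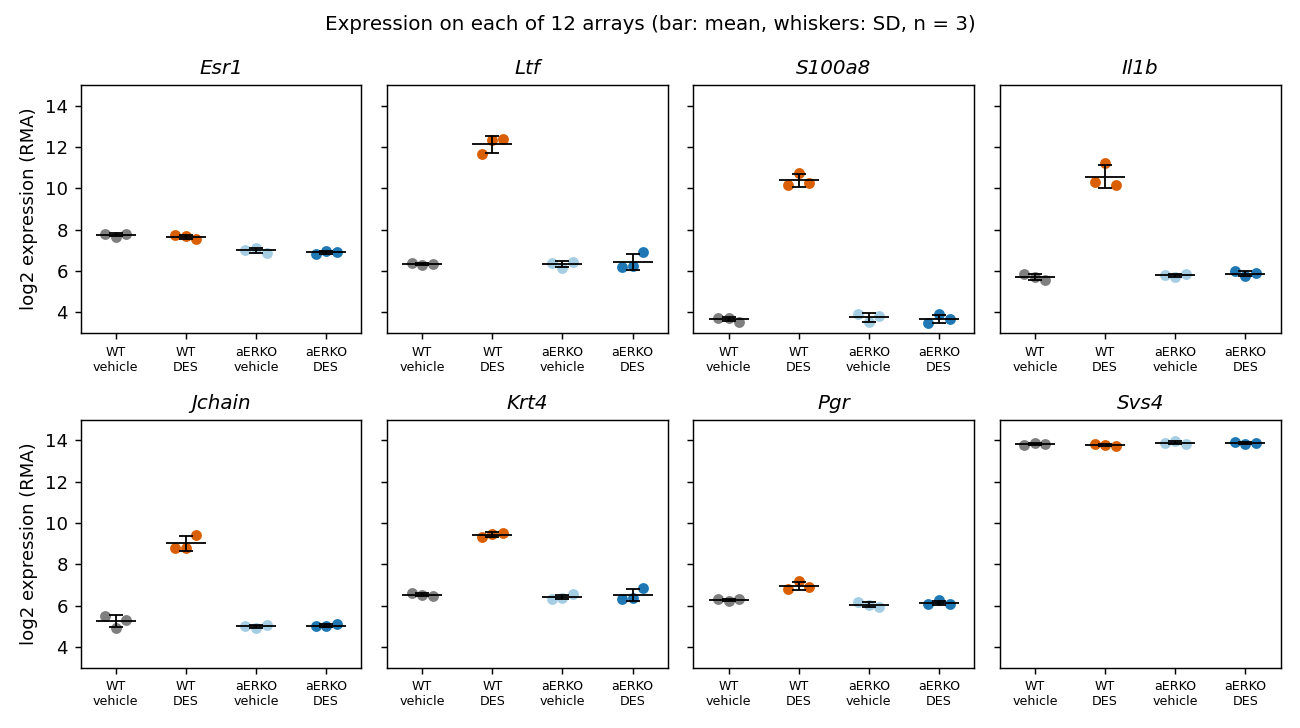
Expression on the log2 scale (RMA) of 8 genes on each of the 12 arrays, with points for arrays, bars for group means and whiskers for the SD of 3 arrays. Ltf rose from 6.34 to 12.1 and S100a8 from 3.67 to 10.4 after DES in WT, Esr1 was lower in both aERKO groups, and Svs4 lay near 13.8 in WT with and without DES.

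Neonatal DES left the adult WT gland with strongly raised transcripts of innate immune, inflammatory and squamous epithelial genes. S100a8, which encodes a calcium-binding protein abundant in neutrophils, was higher in WT_DES than in WT_vehicle by a log2 difference of 6.72 ± 0.15 (SE, adjusted p = 1.02e-11). Ltf, the gene of the iron-binding protein lactoferrin and a classical estrogen target of the mouse uterus, was 55.1-fold higher (5.78 ± 0.20, adjusted p = 2.83e-10). Leaving out immunoglobulin segments, the next largest increases were those of the B cell chemoattractant Cxcl13 (5.44), of S100a9 (5.20), of the cytokine gene Il1b (4.85), of the gasdermin gene Gsdmc2 (4.83) and of the cornified-envelope gene Sprr2f (4.51). Serpina3n, a protease inhibitor, rose by 4.50, Retnlg by 4.23 and Lyz2, which encodes the lysozyme of macrophages, by 4.13. S100a8, Sprr2f and Retnlg lay below the mean of the background controls (5.31) in WT_vehicle, so their baselines were not measured. Their WT_DES levels exceeded that mean by 5.08, 4.17 and 3.82. Decreases were smaller. Smpx, a small muscle protein gene, fell by 2.33 ± 0.18 (5.02-fold), Gad2, a glutamate decarboxylase, fell by 2.13, and the epidermal growth factor gene Egf fell by 2.00. The lipase-related gene Pnliprp1 fell by 1.89, the lysine-degrading enzyme gene Aass fell by 1.83 and the chloride and bicarbonate exchanger gene Slc26a3 fell by 1.79.

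In this comparison limma called 8829 of the 20102 genes tested, 4152 higher and 4677 lower, at an adjusted p below 0.05, and 10698 at an unadjusted p below 0.05. With a fold of at least 2 the counts were 922 higher and 107 lower. The 2 groups did not overlap for 60.9% of the genes tested, where chance gives 10%. They did not overlap for any gene named here as changed by DES in WT either. The rule required this of the genes with the largest changes, so it is no added evidence for them. The split into higher and lower genes depended on how the arrays were scaled. Control RNAs added at hybridization read lower by -0.357 in WT_DES than in WT_vehicle. When the arrays were shifted to these controls, the median of all genes moved from -0.05 to 0.31, and 8345 genes were higher and 350 lower. When arrays were shifted to the same median of tested genes, that median was -0.12, with 3404 higher and 7115 lower. Quantile normalization gave -0.10, with 3515 higher and 7142 lower. All 107 genes at least 2-fold lower kept their call with the hybridization controls, and all 922 at least 2-fold higher kept theirs with the median scaling and with quantile normalization. Small declines are given below with the list median relative to the median of all genes.

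Every one of the 24 tested macrophage and dendritic cell genes rose in WT, with a median of 2.13 (camera adjusted p = 1.15e-19; adjusted p = 0.183 with an estimated correlation). Besides Lyz2, the macrophage receptor gene Adgre1 rose by 3.14 and the lysosomal protease gene Ctss by 2.95. Of the neutrophil genes 13 of 17 rose, with a median of 1.85 (3.69e-11; adjusted p = 0.183 with an estimated correlation), and the 4 others did not pass. The neutrophil list shared 2 members with other lists, and Ltf is 1 of them. Of the 15 B and plasma cell genes 12 rose and 1 fell, with a median of 1.05 (2.75e-08; adjusted p = 0.183 with an estimated correlation). Jchain, which joins secreted immunoglobulin M and A units, rose by 3.76, the heavy chain gene Ighm by 3.59 and the B cell surface gene Ms4a1 by 2.85. Jchain and Ms4a1 lay below the background controls in WT_vehicle, and their WT_DES levels exceeded these by 3.71 and 2.23. The member that fell by 1.54 was Derl3, a gene of protein quality control in the endoplasmic reticulum that secretory epithelia also use. Of 17 T cell genes 13 rose, at a lower median of 0.53 (1.34e-06; adjusted p = 0.216 with an estimated correlation), among them the interleukin 7 receptor gene Il7r (2.28), Cd4 (1.49) and Icos (1.48). In WT_vehicle Il7r was level with the background controls (both 5.31), so the size of its rise is uncertain.

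Programs that immune cells and epithelia share rose with them. Of the inflammatory cytokine and acute phase genes 24 of 26 rose, with a median of 1.87 (camera adjusted p = 1.34e-18; adjusted p = 0.183 with an estimated correlation). Pigr, the epithelial receptor that carries antibodies into secretions, rose by 3.92, the acute phase gene Saa3 by 3.80 and the chemokine gene Ccl8 by 3.66. Saa3 and Ccl8 lay below the background controls in WT_vehicle, and their WT_DES levels exceeded these by 3.58 and 3.26. Of the interferon response genes 21 of 23 rose, with a median of 1.03 (7.35e-12; adjusted p = 0.186 with an estimated correlation), led by Cxcl9 (3.99) and the guanylate-binding protein gene Gbp2 (3.31). Of the antigen presentation genes 15 of 16 rose, with a median of 1.13 (2.84e-10; adjusted p = 0.191 with an estimated correlation), including the class II genes H2-Ab1 (2.32) and H2-Eb1 (2.21). Of 21 glutathione and oxidative defence genes 11 rose and 3 fell, with a median of 0.24 (0.00124; adjusted p = 0.183 with an estimated correlation), against 15 and 0 with the hybridization controls. Gsto1 rose by 2.48, the heme oxygenase gene Hmox1 by 1.59 and Gpx3 by 1.54. Of 20 immediate early genes 10 rose and 1 fell, with a median of 0.24 (0.0197; adjusted p = 0.534 with an estimated correlation), among them Dusp1 (1.06) and Fosl2 (0.89).

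Stromal, vascular, basal epithelial and proliferation genes were also higher in WT_DES. Of the 23 fibroblast and matrix genes 22 rose, with a median of 1.41 (camera adjusted p = 5.49e-16; adjusted p = 0.183 with an estimated correlation). The small proteoglycan genes Lum and Dcn rose by 3.47 and 1.96, and the collagen cross-linking enzyme gene Lox by 1.91. Of 14 endothelial genes 10 rose, with a median of 0.48 (5.36e-05; adjusted p = 0.183 with an estimated correlation), including Cdh5 (1.22) and Pecam1 (1.14). Of the 18 basal and squamous epithelial genes 14 rose and 1 fell, with a median of 0.79 (2.67e-08; adjusted p = 0.183 with an estimated correlation). Ly6d rose by 3.30 and the keratin genes Krt4 and Krt15 by 2.92 and 2.42. The wider collagen and keratin families, looked at after their values were seen, did not rise as a whole. Of 41 collagen genes 14 rose and 11 fell, and of 43 keratin genes 10 rose and 8 fell. Of 28 cell cycle genes 22 rose and none fell, with a median of 0.76 (1.22e-09; adjusted p = 0.319 with an estimated correlation), among them the proliferation marker Mki67 (1.73) and the topoisomerase gene Top2a (1.13). The luminal epithelial list depended on the scaling: 7 of 19 rose and 6 fell, against 10 and 0 with the hybridization controls and 6 and 7 with the median scaling. Its median of 0.06 was 0.42 and -0.01 under these, and camera gave an adjusted p of 0.708. Krt7 rose by 0.84 and Cdh1 by 0.64. Rab25 and Cldn3 fell by 0.68 and 0.63, and both were without a call after shifting to the hybridization controls.

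Estrogen-responsive genes of the female tract included several large increases and some decreases, down to -1.29. Of 22 tested, 10 rose and 4 fell (13 and 1 with the hybridization controls, 9 and 7 with the median scaling), with a median of 0.19 against a mean of 0.91 (camera adjusted p = 0.00659; adjusted p = 0.509 with an estimated correlation). Besides Ltf and Sprr2f, the calcium-activated chloride channel regulator gene Clca3a1 rose by 3.41 and Sprr2b by 2.67. The progesterone receptor gene Pgr rose by 0.67 ± 0.10 (adjusted p = 0.000185). Of 9 sex steroid receptor and co-regulator genes 2 rose and 2 fell (4 and 1 with the hybridization controls), with a median of -0.09 that turned to 0.26 with those controls (camera adjusted p = 0.92). The coactivator gene Ncoa3 rose by 0.77 and the transcription factor gene Gata2 fell by 0.84. Esr2, the gene of estrogen receptor beta, fell by 0.42, and its difference was -0.07 without a call after shifting to the hybridization controls. Of 10 steroid metabolism genes 4 rose (7 higher and 0 lower with the hybridization controls, 3 and 1 with the median scaling), among them the glucuronosyltransferase gene Ugt2b34 (2.32, or 1.26 above the background controls, below which it lay in WT_vehicle) and Cyp1b1 (1.25), and the list as a whole did not pass (median 0.11, camera adjusted p = 0.0729). Of 17 androgen-responsive genes 5 rose and 7 fell, against 6 and 1 with those controls, with a median of -0.25 that turned to 0.10 (camera adjusted p = 0.778). The metalloreductase gene Steap4 rose by 1.80, while Azgp1 and the prostaglandin-inactivating enzyme gene Hpgd fell by 1.45 and 0.64, the latter without a call with those controls.

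The secretory and contractile programs of the gland were modestly lower. Of 14 genes of seminal vesicle secretory proteins 9 fell and none rose, with a median of -0.27, or -0.22 relative to all genes (camera adjusted p = 0.00167; adjusted p = 0.534 with an estimated correlation). Spink1, a protease inhibitor of the secretion, fell by 0.93 ± 0.21 and Svs1 fell by 0.42. The transglutaminase gene Tgm4, which is also on the prostate and coagulating gland list, fell by 0.70. After shifting to the hybridization controls the median was 0.09 and 1 of the 14 stayed lower. Svs4, whose signal was among the highest, did not differ detectably (13.8 ± 0.0361 in WT_vehicle and 13.8 ± 0.0349 in WT_DES, SD, n = 3). Like Svs1 (14.0 in WT_vehicle) and Tgm4 (13.6), it lies close to the top of the array's scale, at 14.54 on 1 WT_vehicle array, where a change reads smaller. Of 26 genes of endoplasmic reticulum (ER) stress and protein secretion 15 fell and 1 rose, with a median of -0.35, or -0.30 relative to all genes (0.00143; adjusted p = 0.534 with an estimated correlation). Sdf2l1 fell by 0.77 and the translocon gene Sec61b fell by 0.68. With the hybridization controls the median was 0.01, with 3 higher and 1 lower. Of 19 smooth muscle genes 12 fell and none rose, with a median of -0.43, or -0.38 relative to all genes (0.00124; adjusted p = 0.534 with an estimated correlation). Pgm5 fell by 0.72 and the smooth muscle actin gene Actg2 fell by 0.67. Shifted to those controls, the smooth muscle median was -0.07, with 1 higher and 1 lower.

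Of 36 genes of DNA methylation and chromatin enzymes 14 rose and 3 fell (25 and 0 with the hybridization controls, 11 and 7 with the median scaling), with a median of 0.16 (camera adjusted p = 0.0329; adjusted p = 0.534 with an estimated correlation). The maintenance methyltransferase gene Dnmt1 rose by 0.58 and the methylcytosine dioxygenase gene Tet2 by 0.62. Of 23 genes that pattern the Wolffian duct, from which the seminal vesicle forms, 5 rose and 5 fell (median 0.09, camera adjusted p = 0.354), against 15 and 1 with the hybridization controls (median 0.44). The growth factor gene Fgf7 rose by 1.05 and Hoxd13 by 0.88, whereas Hoxb13 and Bmp7 fell by 0.95 and 0.70, Bmp7 without a call with those controls. Of 13 Müllerian duct genes 3 rose and 2 fell (median 0.08, camera adjusted p = 0.512), against 7 and 0 with those controls and 3 and 4 with the median scaling. Runx1 rose by 1.16, and Lhx1 fell by 0.36 with a difference of 0.00 after shifting to the hybridization controls. Markers of neighbouring tissues did not pass as lists. Of 13 prostate and coagulating gland genes 1 rose and 5 fell (3 and 3 with the hybridization controls), the latter including the gasdermin gene Gsdma, which fell by 1.44 (median -0.42, camera adjusted p = 0.131). Among 5 epididymis and vas deferens genes the one that fell by 0.24 was Pate4, which is also on the seminal vesicle secretory list. Its difference was 0.12 after shifting to the hybridization controls. The list median was -0.16, or 0.20 with those controls (camera adjusted p = 0.356). None of 13 adipocyte genes passed limma's threshold (median -0.06, or 0.30 with those controls; camera adjusted p = 0.92). Of 16 skeletal muscle genes 3 rose and 3 fell (7 and 1 with those controls), with Myl1 up by 0.77 and Acta1, which fell by 0.75 (median -0.02, or 0.33 with those controls; camera adjusted p = 0.898). Of 10 nerve and Schwann cell genes 2 rose (2 higher and 2 lower with the median scaling), 1 of them the sodium channel gene Scn7a (1.89; list median -0.03, or 0.32 with those controls; camera adjusted p = 0.708).

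Adjusted over the list alone, the counts of changed members in WT were the same or larger, except for 1 fewer lower skeletal muscle gene. They were 11 lower secretory genes, 8 lower androgen-responsive genes, 15 higher DNA methylation genes, 5 higher and 4 lower Müllerian genes, 23 higher cell cycle genes, 11 higher endothelial, 22 higher interferon, 25 higher inflammatory, 11 higher immediate early and 13 higher glutathione genes. The smooth muscle list gave 1 higher and 12 lower, and the skeletal muscle list 3 higher and 2 lower. In all, camera with its preset correlation called 18 of the 29 lists, 15 up and 3 down. None was called with a correlation estimated from the arrays (smallest adjusted p = 0.183). The rotation test fry, which asks whether the genes of a list move one way, called 20.

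**Figure D2:**
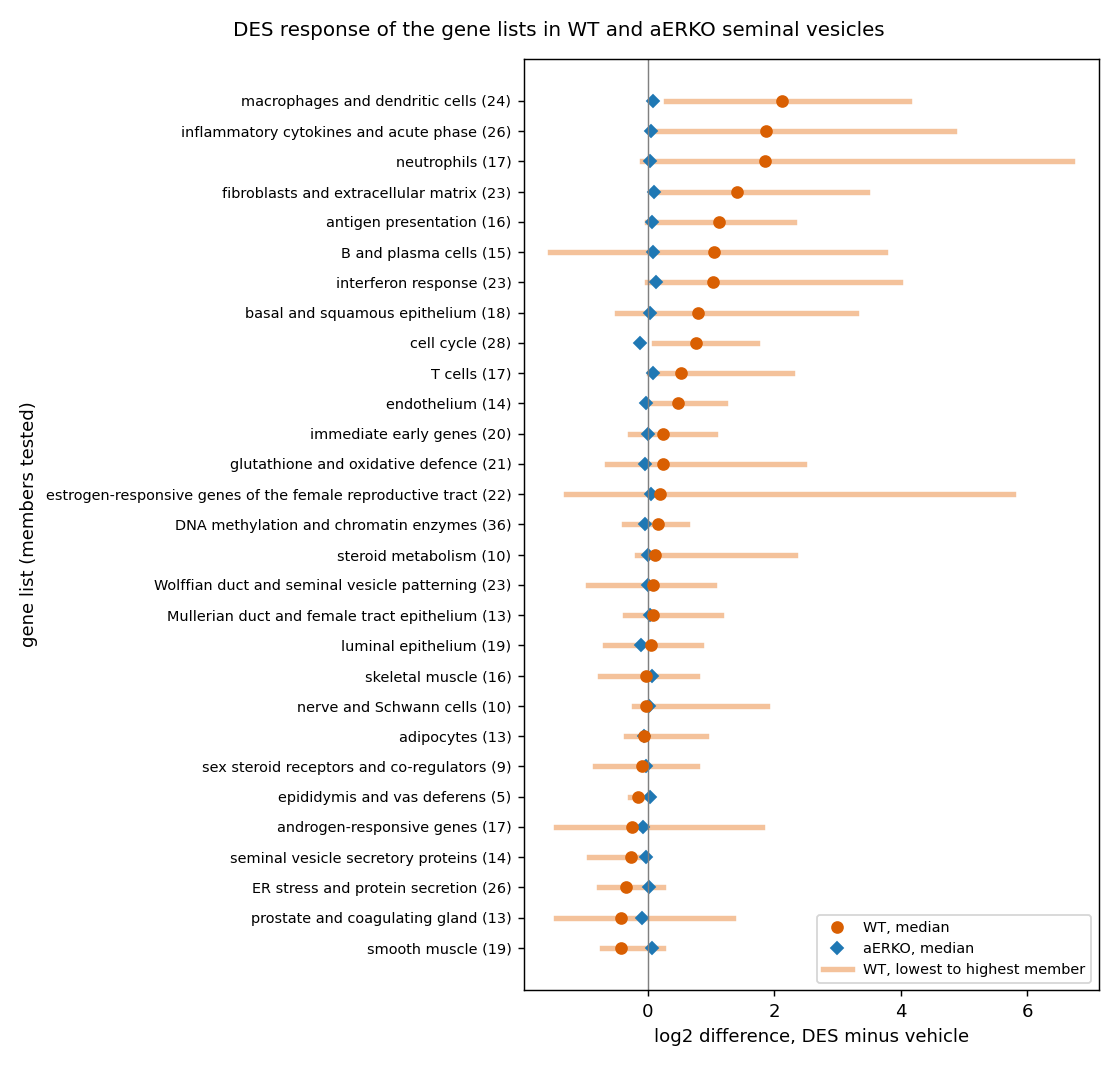
Median log2 difference (DES minus vehicle) of each gene list in WT (circles) and aERKO (diamonds), with pale bars from the lowest to the highest member in WT and the number of members tested in brackets. WT medians reach 2.13 for macrophage and dendritic cell genes, while the aERKO medians lie between -0.12 and 0.12.

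In aERKO seminal vesicles DES left no gene past the threshold, neither the immune genes nor the female-tract and squamous genes that had risen in WT. S100a8 was 3.75 ± 0.208 (SD, n = 3) in aERKO_vehicle and 3.69 ± 0.207 in aERKO_DES, and Ltf was 6.33 ± 0.141 and 6.45 ± 0.391. The log2 differences of Il1b, Jchain, Krt4 and Pgr were 0.08, 0.04, 0.09 and 0.08, all with adjusted p = 0.999. limma called 0 of 20102 genes, with 264 at an unadjusted p below 0.05 and differences from -0.69 to 1.19. Genes simulated in this comparison with a log2 change of 1 were recovered in 96% of cases and those with 0.5 in 66%. The simulated data also held genes with changes of 2 and 3, which ease the adjusted threshold. No gene was called here, so these shares overstate what could be detected. Changes of about 1 are therefore open too, as Nt5c2 did not pass at 1.19 (limma adjusted p = 0.999). When aERKO_DES replicate 1 was left out, 1 gene passed, Mid1, at 0.95 ± 0.09 (adjusted p = 0.0087), against 0.62 with all arrays. Without aERKO_DES replicate 2 it was Nt5c2, at 1.79 ± 0.13 (adjusted p = 0.000504), against 1.19 with all arrays. These 2 genes were chosen after their values were seen.

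No member of any list passed limma's threshold in aERKO, over all genes or adjusted over the list alone. Camera with its preset correlation nevertheless called 11 lists for small shifts, with medians of 0.10 for fibroblast genes, 0.09 for T cell and for B and plasma cell genes, 0.08 for macrophage, 0.07 for antigen presentation, 0.12 for interferon, 0.05 for inflammatory, 0.06 for smooth muscle and 0.07 for skeletal muscle genes. The cell cycle and luminal epithelial medians were -0.12 and -0.10, and turned to 0.01 and 0.03 with the hybridization controls. Several shifts rested on 1 array. Without aERKO_DES replicate 3 the medians were 0.0073 for T cell, 0.0029 for B and plasma cell and 0.0074 for antigen presentation genes. They were -0.030 for inflammatory and -0.0077 for skeletal muscle genes. With all arrays, the smallest adjusted p of camera was 0.723 with an estimated correlation, and fry called none (smallest adjusted p = 0.668).

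The test of the difference itself, the response to DES in WT minus that in aERKO, passed for 4679 genes, 2838 with a higher and 1841 with a lower response in WT. With a fold of at least 2 the counts were 909 and 67. Ltf differed by 5.66 (adjusted p = 2.4e-08), S100a8 by 6.79 (6.62e-10), Krt4 by 2.83 (1.68e-07) and Pgr by 0.59 (0.0101). Among the largest lower responses, Smpx differed by -2.03 (adjusted p = 0.000132), Gad2 by -2.05, Egf by -1.94 and Pnliprp1 by -1.82. The split moved with the scaling, to 2806 higher and 133 lower with the hybridization controls, 2407 and 3834 with the median of tested genes, and 2595 and 4288 with quantile normalization. The 922 genes at least 2-fold higher in WT had a median response of 1.66 in WT and 0.05 in aERKO (0.04, 0.07 and 0.02 without aERKO_DES replicates 1, 2 and 3 in turn), and the 107 lower genes -1.19 and -0.11 (-0.17, -0.19 and -0.02), for groups that share no array. Shifted to the hybridization controls, the 2 medians in aERKO were 0.18 and 0.02. For the lower genes that in aERKO was -0.07 without aERKO_vehicle replicate 2.

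**Figure D3:**
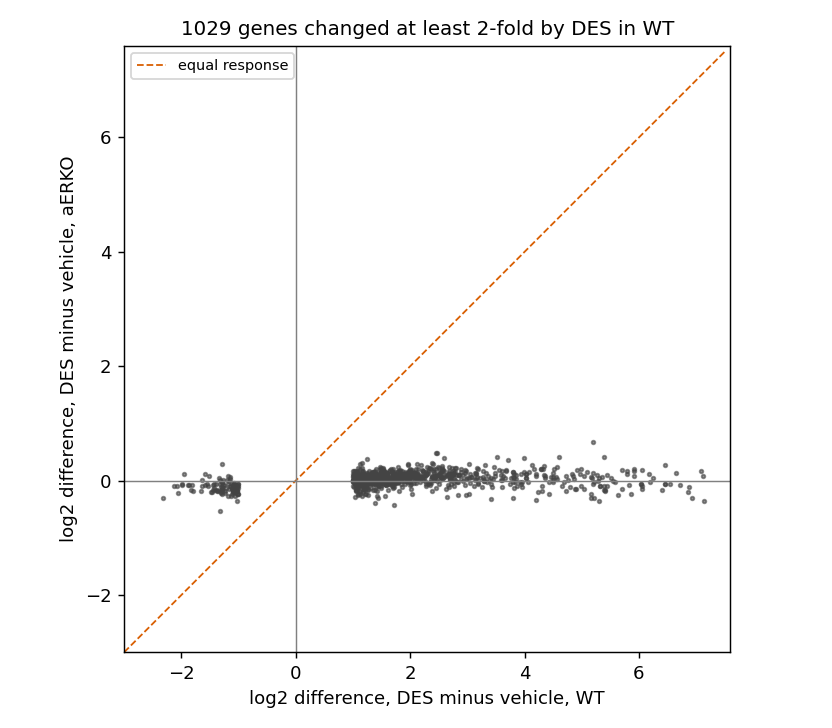
Log2 difference (DES minus vehicle) in aERKO against that in WT for the 1029 genes changed at least 2-fold in WT, 1 point per gene, with a dashed line where both would be equal. The points lie along 0 on the aERKO axis, where the largest absolute value is 0.68.

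By list, the interaction was largest for macrophage and dendritic cell genes, of which 22 of 24 passed (median 2.08), and for neutrophil genes, 13 of 17 (1.78). Other lists with higher responses in WT included inflammatory genes with 24 of 26 (1.72), fibroblast and matrix genes with 21 of 23 (1.31), cell cycle genes with 20 of 28 (0.87) and basal and squamous genes with 13 of 18 (0.81). Lower responses in WT passed for 11 of 19 smooth muscle genes (median -0.46), 5 of 14 secretory genes (-0.25) and 8 of 26 ER stress and secretion genes (-0.37). With the hybridization controls 1 smooth muscle gene and 0 secretory or ER stress genes had a lower response by limma, and the medians were -0.24, -0.02 and -0.15. Adjusted over the list alone the counts were 23, 13, 24, 22, 22 and 14 higher and 12, 6 and 11 lower, in the same order. Camera called 17 of the 29 lists, 14 up and 3 down. None was called when the correlation was estimated, where the macrophage, neutrophil and inflammatory lists had adjusted p = 0.158 with an estimated correlation and the 3 lower lists had adjusted p = 0.529 with an estimated correlation. The rotation test fry called 17 lists.

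Given vehicle, aERKO and WT glands differed in few genes. Esr1 and Timp1, an inhibitor of matrix metalloproteinases, were lower in aERKO by a log2 difference of -0.76 and -0.80, each with an adjusted p of 0.00587. Ms4a5 was lower (-2.59 ± 0.37, adjusted p = 0.0493). Atp13a4, a cation-transporting ATPase gene, was higher by 1.48 (0.00624) and Ptgds, a prostaglandin D synthase gene, by 0.92 (0.019). These 5 were all the genes called by limma, with 864 at an unadjusted p below 0.05. The count depended on the setting: 14 were called with the hybridization controls, and array weights gave more still, as listed in the closing part. In each of the 5 the 3 arrays of one group lay beyond all 3 of the other. The calls depended on single arrays. Esr1, Timp1 and Atp13a4 were called without WT_vehicle replicate 1 or replicate 2, and no gene was called without WT_vehicle replicate 3 (smallest adjusted p = 0.0502). Without aERKO_vehicle replicate 1 all but Ms4a5 were called, and without replicate 2 or replicate 3 only Esr1 and Timp1.

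Adipocyte genes stood out among the lists in this comparison. Their median was -0.68 in aERKO_vehicle, none of the 13 passed over all genes, and 10 were lower adjusted over the list alone (camera adjusted p = 6.93e-14; adjusted p = 0.962 with an estimated correlation). The fatty acid binding protein gene Fabp4 differed by -1.40, the fatty acid transporter gene Cd36 by -1.25 and Retn, the gene of the adipocyte hormone resistin, by -1.01. The WT_vehicle arrays themselves were far apart, with Fabp4 at 9.04, 6.68 and 7.70 against 6.23, 6.69 and 6.30 in aERKO_vehicle. The list median was -0.26 without WT_vehicle replicate 1 and -1.05 without replicate 2. Camera called 7 further lists for small shifts, up for secretory (0.06), cell cycle (0.05) and smooth muscle genes (0.10) and down for fibroblast (-0.12), antigen presentation (-0.06), interferon (-0.12) and prostate and coagulating gland genes (-0.27), all with adjusted p = 0.962 with an estimated correlation. The rotation test fry called none of the 29 (smallest adjusted p = 0.984). Each of these 7 calls was lost when some single array was left out. The prostate median was -0.06 without WT_vehicle replicate 1 and -0.16 without aERKO_vehicle replicate 1, that of fibroblast genes -0.06 without WT_vehicle replicate 1 and -0.11 without aERKO_vehicle replicate 3, and that of interferon genes -0.06 without WT_vehicle replicate 3. Antigen presentation lost its call without WT_vehicle replicate 3 (median 0.00) and aERKO_vehicle replicates 1 or 2 (-0.05 and -0.08), secretory genes without WT_vehicle replicate 1 (0.05) and aERKO_vehicle replicates 1 or 2 (0.07 and 0.03), cell cycle genes without WT_vehicle replicate 1 (-0.03) and aERKO_vehicle replicate 3 (0.02), and smooth muscle genes without aERKO_vehicle replicate 2 (0.07).

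Given DES, aERKO glands had lower levels of immune, inflammatory and stromal genes than WT glands and higher levels of smooth muscle genes. This comparison shares the WT_DES arrays with that of DES in WT, so the 2 are alike in part through those arrays. S100a8 was lower by a log2 difference of -6.70, Ltf by -5.67, Jchain by -3.97 and Pigr by -4.70, and Smpx was higher by 2.40 and Actg2 by 1.07. limma called 10483 genes, 5529 higher and 4954 lower in aERKO_DES, of which 123 and 970 differed at least 2-fold. With the hybridization controls 553 were higher and 5825 lower, with the median of tested genes 7974 and 3917, and with quantile normalization 7692 and 3890. All 24 macrophage and dendritic cell genes, 25 of 26 inflammatory genes and 21 of 23 fibroblast genes were lower, with medians of -2.09, -1.85 and -1.43 (adjusted p = 0.227 with an estimated correlation for each). Of 19 smooth muscle genes 15 were higher (median 0.62, adjusted p = 0.428 with an estimated correlation), and of 14 secretory genes 11 were (0.34, adjusted p = 0.494 with an estimated correlation). With the hybridization controls 10 smooth muscle genes and 1 secretory gene were higher. Of 13 adipocyte genes 7 were lower, with a median of -0.82 (camera adjusted p = 0.02; adjusted p = 0.641 with an estimated correlation), Fabp4 among them at -2.59. In all, camera called 18 lists, 3 up and 15 down, none was called with an estimated correlation, and fry called 21.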

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

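The tests of array-wide scaling for the immune genes and small declines, of the main cell type's share, of immune cells of several types and of uniform dilution, and every value after shifting to the hybridization controls, were chosen after the results were seen. The response to DES differed between WT and aERKO for 4679 genes by a test of the difference itself, and the values below are the response in WT minus that in aERKO (log2). Among innate immune and inflammatory genes S100a8 differed by 6.79, Ltf by 5.66, Cxcl13 by 5.35, S100a9 by 5.07, Il1b by 4.77, Retnlg by 4.42, Serpina3n by 4.35, Pigr by 3.95, Lyz2 by 3.85, Saa3 by 3.83, Ccl8 by 3.61, Cxcl9 by 3.60, Gbp2 by 3.04, Adgre1 by 3.03 and Ctss by 2.81. S100a8, Retnlg, Saa3, Ccl8, Jchain, Ms4a1, Sprr2f and Ugt2b34 lay below the background controls in the 3 groups other than WT_DES, so the size of their differences and their order rest on baselines that were not measured. Il7r lay level with those controls in WT_vehicle and aERKO_vehicle (5.31 and 5.32), so its difference is uncertain too. Among lymphocyte and antigen presentation genes Jchain differed by 3.72, Ighm by 3.49, Ms4a1 by 2.76, Il7r by 2.19, H2-Ab1 by 2.15, H2-Eb1 by 2.11, Cd4 by 1.35, Icos by 1.34 and Derl3 by -1.48.

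For stromal and endothelial genes the difference was 3.23 for Lum, 1.84 for Dcn, 1.80 for Lox, 1.12 for Timp1, 1.26 for Cdh5 and 1.14 for Pecam1. Epithelial genes gave 4.72 for Gsdmc2, 4.49 for Sprr2f, 3.37 for Clca3a1, 3.30 for Ly6d, 2.83 for Krt4, 2.74 for Sprr2b, 2.41 for Krt15, 0.82 for Krt7, 0.80 for Cdh1 and -0.55 for Rab25. It was 2.15 for Mki67 and 1.37 for Top2a. Receptor, steroid and androgen-responsive genes gave 2.36 for Ugt2b34, 1.99 for Steap4, 1.28 for Cyp1b1, 0.77 for Ncoa3, 0.59 for Pgr, -0.42 for Esr2, -0.68 for Gata2, -1.28 for Azgp1 and -0.63 for Hpgd. Enzyme, stress and patterning genes gave 2.49 for Gsto1, 1.56 for Hmox1, 1.37 for Gpx3, 0.91 for Dusp1, 0.89 for Fosl2, 0.65 for Dnmt1, 0.65 for Tet2, 1.11 for Fgf7, 0.85 for Hoxd13, 1.17 for Runx1, -0.71 for Hoxb13 and -0.52 for Bmp7.

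Secretory and contractile genes differed the other way, by -0.90 for Spink1, -0.68 for Tgm4, -0.74 for Sdf2l1, -0.60 for Sec61b, -0.86 for Pgm5 and -0.81 for Actg2. With the hybridization controls, of these 6 only Pgm5 kept its call, and Rab25, Esr2, Gata2, Hpgd, Hoxb13, Bmp7, Acta1 and Spock1 lost theirs. Among the genes named here, the largest of the other lower responses were -2.05 for Gad2, -2.03 for Smpx, -1.94 for Egf, -1.82 for Pnliprp1, -1.70 for Pate8, -1.68 for Aass, -1.65 for Orm3, -1.60 for Slc26a3 and -1.36 for Gsdma. Markers of neighbouring tissues gave 1.83 for Scn7a, 0.77 for Myl1 and -0.77 for Acta1, and Spock1, chosen after its values were seen, gave -0.39.

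The same test by list gave medians of 2.08 for macrophage and dendritic cell, 1.78 for neutrophil, 1.72 for inflammatory, 1.31 for fibroblast and matrix, 1.04 for antigen presentation, 0.94 for B and plasma cell, 0.87 for interferon, 0.87 for cell cycle, 0.81 for basal and squamous, 0.59 for T cell, 0.58 for endothelial, 0.37 for glutathione, 0.15 for DNA methylation and 0.10 for estrogen-responsive genes. Lower responses had medians of -0.46 for smooth muscle, -0.37 for ER stress and secretion and -0.25 for secretory genes. After shifting to the hybridization controls these 3 were -0.24, -0.15 and -0.02. With these controls and with the median scaling, the estrogen-responsive median was 0.32 and 0.02, that of DNA methylation genes 0.38 and 0.07, and that of glutathione genes 0.59 and 0.28. None of these 17 lists was called with an estimated correlation (adjusted p from 0.158 to 0.529). Outside the gene-level comparisons, 3887 of 18612 tested probe sets without a single gene symbol also changed after DES in WT, against 1 in aERKO.

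A scaling moves every gene of an array alike, so array-wide scaling alone cannot make the rise of immune genes after DES in WT: the 73 tested members of the 4 immune lists moved above the median of all genes by 1.52 (largest within-group SD 0.149). A lower share of the main cell type would raise the markers of every other type alike. The macrophage list instead moved above the mean of the endothelial, nerve and adipocyte lists by 1.65, beyond the largest within-group SD of 0.307. That test covered the macrophage list alone, and the fibroblast and matrix list was not in that mean. The fibroblast median of 1.41 exceeded those of B and plasma cell (1.05) and T cell genes (0.53). For B, plasma and T cell genes a lower share therefore stays open. More immune cells of several types in the tissue may account for part of the rise, since 4 of 4 immune lists had most of their tested members called higher. The T cell part is weaker. Its member Thy1 is also on the fibroblast and matrix list, of which 22 of 23 genes rose. Only 1 of 53 T cell receptor variable segments was called, or 21 with the hybridization controls. The member with the highest signal after DES was Lyz2 (8.73 to 12.9) for macrophages, Ighm (7.32 to 10.9) for B and plasma cells, Ltf (6.34 to 12.1) for neutrophils and Thy1 (8.24 to 9.06) for T cells. In WT_vehicle 21 of 24, 9 of 15, 9 of 17 and 12 of 17 members already lay above the array median, and epithelial cells can express some of them, Ltf among them, so induction in resident cells stays open.

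The small declines after DES in WT moved with the scaling of the arrays, which leaves their source open. Of the 4570 genes called lower by less than 2-fold, 5.32% were still called lower after shifting to the hybridization controls. That shift, 0.357, exceeds the median size of these declines, 0.341, so it would end most of the calls whatever their source, and array-wide scaling and a real decline cannot be told apart for them. Uniform dilution of resident cells by incoming cells would lower all resident types alike. The endothelial score moved above the smooth muscle score by 0.840 (largest within-group SD 0.116) and the basal epithelial score by 1.46 (0.219). The luminal score did so by 0.372 (0.169), under 3 times its SD, which leaves dilution open for luminal and smooth muscle genes. Resident types thus did not all move alike. The endothelial list was chosen when the list medians were known, so it is no independent test of dilution. Lower responses in WT than in aERKO passed for 11 of 19 smooth muscle and 5 of 14 secretory genes, against 1 and 0 with the hybridization controls. A loss of these transcripts through the receptor therefore stays open.

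The lower adipocyte genes of aERKO_vehicle rest on WT_vehicle arrays that lie far apart. Their mean scores were 8.63, 7.38 and 7.81, against 7.26, 7.44 and 7.18 in aERKO_vehicle. Fat carried along with 1 or 2 WT_vehicle samples and a stable difference by genotype cannot be told apart here. The lowest WT_vehicle score lay -0.0618 from the highest aERKO score for both tests, so the groups overlapped. This gap was judged against the largest within-group SD, 0.635. That SD is the spread of the WT_vehicle arrays themselves, so the further apart they lie, the less the tests can decide. All 13 tested members lay above the array median in WT_vehicle. In WT_DES the scores were 8.07, 7.91 and 8.02, and in aERKO_DES 7.20, 7.14 and 7.28.

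Other splits of the samples were counted for each comparison. With 3 arrays against 3 there are 10 splits, so a share under 0.05 cannot be reached. For DES in WT 1 of the 10 splits, the real one, gave as many as 8829 genes (highest other 0), and 5 gave as many as 18 lists (highest other 20). For DES in aERKO 10 of 10 gave at least the real count of 0 genes by limma (264 at an unadjusted p below 0.05 in the real split; highest other 0), and 4 gave as many as 11 lists (highest other 15). Given vehicle, 1 of 10 gave as many as the 5 genes that differed by genotype (highest other 0) and 10 gave as many as 8 lists (highest other 16). Given DES, 1 of 10 gave as many as 10483 genes (highest other 0) and 3 as many as 18 lists (highest other 19). For the difference between responses 100 splits were drawn, of which 7 gave as many as 4679 genes (highest other 8310) and 43 as many as 17 lists (highest other 21). Splits that mixed the WT arrays still kept part of the WT difference, so the share for lists decides nothing. Chance is not excluded for the lists. The share for genes says nothing about chance, because 8 of the splits drawn kept the WT arrays parted by treatment and so kept the whole WT difference. All 7 were among these, and the highest count among splits that mixed the WT arrays was 1, which points to the difference between the WT groups as the structure behind those counts.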

How the results depend on the processing

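The shift to the hybridization controls, leaving out both DES arrays numbered 3 and the comparison of 6 aERKO arrays with WT_vehicle were chosen after seeing the data. The count for DES in WT stayed within 1.5 times of 8829 under every alternative except a fold of at least 2 (1029), and leaving out each array in turn gave 6471 to 9855. For DES in aERKO these counts ran from 0 to 1, and testing every probe set gave 1. For the difference between responses they ran from 3401 to 5713, with 8164 under array weights, 2939 with the hybridization controls and 976 with a fold of at least 2. Given vehicle, the genotypes differed in 0 to 6 genes when each array was left out, in 8 with only the 2 groups compared, 80 under array weights, 14 with the hybridization controls and 2 with a fold of at least 2. Given DES the range was 7614 to 10947, with 6771 under the stricter filter, which tests fewer genes, 6378 with the hybridization controls, 1093 with a fold of at least 2 and 18161 for every probe set, where more are tested. Except where fewer or more were tested or a fold was added, the cause was not tested.

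The number of lists called by camera fell to 0 with an estimated correlation in all 5 comparisons. The rotation test fry gave 0 for DES in aERKO and for genotype given vehicle. Array weights left 3 lists for DES in aERKO and 5 for genotype given vehicle, and leaving out both DES arrays numbered 3 left 5 for genotype given vehicle.

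With the hybridization controls the change of Lhx1 after DES in WT turned to 0.000704 and that of Pate4 to 0.12. Some list medians near 0 changed sign. For DES in aERKO, array weights gave -0.0207 for antigen presentation, -0.0249 for B and plasma cell, -0.0103 for T cell, -0.0101 for skeletal muscle and -0.0148 for inflammatory genes. Leaving out each array in turn, inflammatory genes ran from -0.0299 (without aERKO_DES replicate 3) to 0.0905, and they were again at -0.0299 without both DES arrays numbered 3. Skeletal muscle genes ran from -0.00773 (without aERKO_DES replicate 3) to 0.114. Smooth muscle genes ran from -0.0127 (without aERKO_DES replicate 1) to 0.138. Given vehicle, antigen presentation ran from -0.160 to 0.003 (without WT_vehicle replicate 3) and cell cycle from -0.0279 (without WT_vehicle replicate 1) to 0.146. Adipocyte genes after DES in WT ran from -0.221 to 0.216 (without WT_vehicle replicate 1). The cause was not tested for any of these.

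Among the genes chosen by the rule, each taken under each alternative, direction and side of the threshold held in 2995 cases for DES in WT, with 27 losing and 9 gaining a call. For the difference between responses these were 2781, 119 and 7, for genotype given vehicle 2706, 23 and 3, and for genotype given DES 3101, 49 and 2. For DES in aERKO all 2826 cases held.

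The labels do not say that replicate numbers pair the samples. Of 18 pairs of arrays with the same number, 6 correlated above 0.1 around their group means (full range -0.355 to 0.520). These 6 were all the pairs numbered 2 (0.180 to 0.224) and 3 (0.371 to 0.520) among WT_DES, aERKO_vehicle and aERKO_DES. A factor shared by number outside WT_vehicle therefore stays open. With the replicate block the counts were 9988 and 0 for DES in WT and aERKO, 5991 for the difference, and 4 and 11466 for genotype given vehicle and DES. Background control probes read 5.31 in WT_vehicle and 4.87 in WT_DES, so values near that level say little about small changes, as do values near the top of the scale.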

Other observations

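The gene families below were chosen after their values were seen. Immunoglobulin variable segments gave the broadest rise after DES in WT, with 100 of 103 tested heavy chain segments higher (median 4.21) and 72 of 72 tested kappa segments (median 4.11), the largest Igkv5-43 at 7.14. Their responses differed between genotypes for 99 and 70 segments, with medians of 4.10 and 4.04. The array named 117 heavy chain and 86 kappa segments. Testing needed a value above the array median on at least 3 arrays, as many as WT_DES holds. A segment low in all other groups was therefore tested only if high throughout WT_DES, which raises these shares. Whether the segments rose separately from one another was not tested. T cell receptor variable segments showed no such rise, with 1 of 53 called, Trbv20 at 2.03, and 21 after shifting to the hybridization controls. Among chemokine ligands 26 of 31 rose (median 1.24), among Fc receptors 7 of 7 (2.31), among toll-like receptors 8 of 10 (0.88) and among guanylate-binding proteins 7 of 7 (2.49), and their responses differed between genotypes for 24, 7, 8 and 7.

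Among families that declined, the 5 tested members of the Pate family of sperm-associated proteins all fell in WT (median -0.82), led by Pate8 at -1.59, and 3 of 5 were called lower with the hybridization controls. All 3 orosomucoid genes fell (median -1.19), Orm3 by 1.64, and 3 of 3 were called lower with those controls. Of 290 solute carrier genes 51 rose and 105 fell (median -0.18), which turned to 79 and 22 (median 0.18) with those controls. Collagens and keratins went both ways. Of 41 collagen genes 14 rose and 11 fell (median -0.11), against 16 and 1 with those controls. Of 43 keratin genes 10 rose and 8 fell (median -0.14), against 12 and 0. None of these families had a member called by limma in aERKO, in the comparison that called 0 genes, with 264 at an unadjusted p below 0.05.

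When all 6 aERKO arrays were set against WT_vehicle, 6 genes were called, the 5 that differed given vehicle and Spock1, a matrix proteoglycan gene, at 0.47 (adjusted p = 0.0461). A chromosome segment carried with the targeted allele could make genes near Esr1 differ by genotype. Of the 40 nearest tested neighbours 2 (5.00%) had an unadjusted p below 0.05 in this comparison of 6 arrays with 3. Among other genes the share was 6.14% (one-sided Fisher exact p = 0.713), so the neighbours showed no excess. With so few genes the test could miss a segment that altered only some of them, so such a segment stays open.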
